A study of Mus musculus with 6 samples.

How the data were processed

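Per the labels, RNA of whole E8.5 embryos was purified with a Qiagen kit, and 250 ng of each of the 6 samples was labelled with Cy3 and hybridised to an Agilent mouse array. The scanner files hold intensity values made by the authors with Agilent Feature Extraction 9.5, with background subtracted, spatial trends removed and a surrogate value where the signal was not significantly above background. Per the file headers no scaling between arrays was applied, and other columns hold the raw mean intensity of each spot, its local background intensity and flags of 0 or 1 (unit: other) for saturation, outliers and signal well above background. The deposited series table holds intensity values on a linear scale. It equalled the processed signal of the scanner files at 100% of spots within a relative tolerance of 1e-4, so the scanner files were used. No column of it belonged to samples outside the series.

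Control spots and outlier spots (53 to 83 per array) were left out, and replicate spots of a probe were averaged. The processed signal was put on a log2 scale, and each array's 75th percentile was subtracted. That percentile was 1627, 970.4 and 1582 units for CKO 1, 2 and 3, and 1000.1, 1010.0 and 957.5 units for controls 1, 2 and 3. Probes were kept if well above background on all 3 arrays of at least 1 genotype. Of 41174 distinct probes, 32719 were named after 19505 genes of the reference table: 22951 by accession, 6659 by symbol and 3109 by synonym. The remaining 8455 kept the array's own name. Probe coordinates are those of the array's annotation (mm7), and the reference table, of assembly GRCm 38, was used for names only. Saturated spots numbered 4 on CKO 1 and CKO 3 and 0 on the other arrays, and the median coefficient of variation of replicate spots was 11.3% to 14.2% per array.

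CKO was compared with control by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all 27840 probes and a threshold of 0.05. A gene was counted through its probe with the highest mean. Among genes with more than 1 kept probe, 6470 in number, 3 had probes that passed in opposite directions: Dbf4, Tmem243 and Wdr33. For a gene not well above background on any array of a genotype, the fold is a bound against the lowest signal well above background. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 21 lists, and a list of sex-linked genes was read without a test. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took every Smarca4 probe, and the 12 largest rises and 12 largest falls among genes that passed, were well above background on all 6 arrays and had no overlap between genotypes. It added up to 3 genes per direction measured in 1 genotype only, up to 4 members per list with the largest differences among those that passed, or else the member with the smallest p, and all sex-linked genes. Some results are not reported here. Files were read with Python 3.11.15, and matplotlib 3.10.9 drew the plots.

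The alternatives tried were quantile and median scaling, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, the series table's values, an intensity trend with robust eBayes, array weights, slide as a random block, scan day as a fixed block, replicate number as a block, a 2-fold and a stricter threshold, the mean of a gene's probes, an estimated correlation, fry, and each array left out in turn. A labelling batch, inferred from the spike-in signal, was added as a fixed block after seeing the data. Array weights gave a convergence warning. The fit was tested on simulated data with 200 changed probes among 27840. The simulated noise was independent between probes, with no day, slide or batch effect, so the rates need not hold for the real arrays. The fit recovered 13.8%, 80.6% and 98.6% of changes of 1, 2 and 4 on the log2 scale, with 8 false calls among 143. With the labelling batch as a block it recovered 0%, 24.2% and 86.6%, and with scan day as a block 0%, 1.4% and 87.3%.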

Results

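Gene expression was measured in whole mouse embryos at embryonic day 8.5 (E8.5) on 1-colour Agilent arrays, with 1 array per sample. Per the labels, the mother was injected with tamoxifen, and the embryos were either conditional knockouts of Brg1 (Brg1 CKO) or carried the floxed gene and served as wild-type control. Brg1, whose gene symbol is Smarca4, is an ATPase subunit of the SWI/SNF chromatin remodelling complexes. Each genotype had 3 samples, which the labels call biological replicates. Whether a sample was 1 embryo or a pool is not given in the sources used here. Each array carried 43379 spots outside the controls. The share of spots well above background was 73.5% on CKO 1, 68.7% on CKO 2 and 72.9% on CKO 3, against 69.3%, 69.2% and 68.5% on controls 1, 2 and 3. After the filter on dim probes, 27840 probes of 15025 named genes were tested. The number of arrays, 3 per genotype, limits the precision of every difference given.

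The arrays were scanned on 3 days. The 3 controls and CKO 2 shared a day, and CKO 1 and CKO 3 each had a day of their own. The signal of the brightest spike-in control also parted CKO 1 and CKO 3, at 12934 and 6905 units, from the other 4 arrays, where it lay between 208550 and 241121. This split is called the labelling batch below, although no label names such a batch and its cause is not known. The median of each of the 21 tested lists is therefore given with the same-day value, as are many single genes. This is CKO 2 minus the mean of the 3 controls. That value is also the estimate of a model with scan day as a block. The 3 controls shared 1 slide and each CKO array had a slide of its own. A slide difference therefore cannot be told apart from genotype, in the same-day value too. Over all tested probes, the CKO arrays correlated with one another at 0.983 to 0.991 and with the controls at 0.942 to 0.974. CKO 2 was closer to controls 1, 2 and 3 (0.96, 0.973 and 0.974) than CKO 1 (0.942, 0.959 and 0.964) or CKO 3 (0.945, 0.958 and 0.965). CKO 1 and CKO 3, of the other scan days, correlated with each other at 0.991. The controls correlated with one another at 0.967 to 0.991, control 1 being the farthest from the other 2. Correlations here are across probes, which are not independent replicates.

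The targeted gene was lower in every CKO sample. The brightest Smarca4 probe read 1.54, 2.70 and 2.05 in CKO 1, 2 and 3 against 5.33, 4.49 and 4.53 in controls 1, 2 and 3, as log2 signal minus the array's 75th percentile. The difference was -2.69 ± 0.37 (SE, n = 3 and 3), a 6.44-fold fall, with a limma adjusted p of 0.0119. The other 2 probes fell by 2.25 and 2.07 on the log2 scale, with limma adjusted p of 0.00578 and 0.0135. The same-day differences of the 3 probes were -2.08, -2.51 and -1.66. On chromosome 9 of build mm7 the array's annotation places the brightest probe between 21520316 and 21521714, with the sequence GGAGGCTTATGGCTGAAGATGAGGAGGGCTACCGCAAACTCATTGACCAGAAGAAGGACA. The second probe lies at 21582352 to 21582411 and the third at 21514928 to 21514987. An exon annotation of that build was not used here, and the deleted exons are not given in the sources used here, so a probe may lie outside the deleted part and a drop there is no direct reading of the deletion. The brightest probe missed the threshold without CKO 1 (log2 difference -2.41, adjusted p 0.0513) and without CKO 3 (-2.66, 0.0554), as did the third without CKO 1 (0.0719), CKO 3 (0.0598) or control 2 (0.0578). With the labelling batch as a block none of the 3 probes passed (limma adjusted p 0.137, 0.0566 and 0.164), nor with scan day as a block (0.293, 0.189 and 0.343).

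Between the genotypes, 1561 of the 15025 genes changed, 790 of them higher and 771 lower in CKO. Of these, 1147 differed at least 2-fold, 555 upwards and 592 downwards. Falls reached farther than rises: 68 genes fell at least 8-fold and 36 rose at least 8-fold. The largest rise among genes well above background on all 6 arrays was in Dusp16, a phosphatase acting on MAP kinases, which rose by 5.04 ± 0.17 (SE), or 32.9-fold, with a limma adjusted p of 0.000233. Dnmt3l, a cofactor of the DNA methyltransferases in germ cells, rose 25.5-fold and Gfi1, a transcriptional repressor of blood cells, 21.3-fold. The same-day differences were 5.075 for Dusp16, 4.74 for Dnmt3l and 4.51 for Gfi1. Psmb8, a subunit of the immunoproteasome, rose 14.85-fold. Pdyn, the precursor of dynorphin, rose 10.95-fold, Svop 10.2-fold and Gad2, which makes the transmitter GABA, 8.83-fold. Cpb2 at 9.46-fold, Elf5 at 9.40-fold, Lgals3 at 9.035-fold, Bmp8b at 8.965-fold and Cdkn2b at 8.92-fold completed the 12 largest rises among such genes. The 12 largest falls among them were led by Myh7, which encodes a cardiac myosin heavy chain, at 322-fold (-8.33 ± 0.21 on the log2 scale, adjusted p 8.87e-05), with a same-day difference of -8.38. They further comprised Myh6, Myl2, Mybpc3, Myh8, Smpx, Myo18b, Nppa, Actn2, Myh4, Synpo2l and Csrp3, with falls of 30.7-fold to 118.5-fold. Most of these encode parts of the sarcomere, the contractile unit of muscle. The probes of Myh4 and Myh8 could share sequence with the related Myh6 and Myh7, so their own levels are uncertain.

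**Figure D1:**
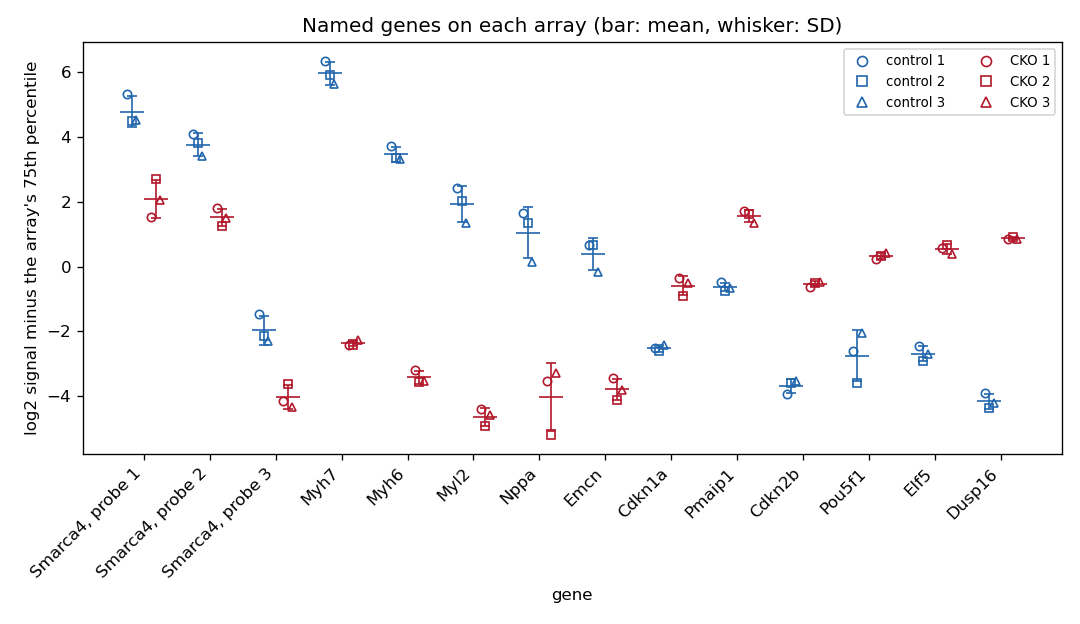
Log2 signal minus the array's 75th percentile (vertical axis) of Smarca4 probes and 11 named genes (horizontal axis) on each of the 3 control arrays (blue) and 3 CKO arrays (red). Horizontal bars are means and whiskers are SD over 3 arrays. The 3 CKO values and the 3 control values did not overlap for any gene drawn, and Myh7 stood at -2.36 in CKO against 5.97 in control. Apart from Smarca4, the genes were chosen for passing the test, and many also for having no overlap, so the lack of overlap was largely fixed by that choice.

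Some genes were measured on the arrays of 1 genotype only. Nanog, a transcription factor of pluripotent cells, was not well above background in any control and was at least 7.78-fold higher in CKO. Klk1b24 was at least 6.97-fold and the dopamine receptor gene Drd3 at least 4.89-fold higher. Islr, Abra and Casq1 were not well above background in any CKO sample and were at least 37.4-fold, 32.1-fold and 13.2-fold lower there. Abra and Casq1 are muscle genes. Outside the rule for named genes, the following are given because of their values, which had been seen: Tnnc1, Nppb, Myocd, Tbx5, Nkx2-5, Tbx20, Hand1, Ccng1, Phlda3, Trp53inp1, Mdm2, Cdkn2c, Sox1 and Sox17. Among the changed genes, 74 were not well above background on any control array and 39 on any CKO array.

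In all 1561 changed genes CKO 2 lay beyond all 3 same-day controls on the side of the change, although CKO 2 had itself entered the selection. Over all genes that share was 60.1%, on either side. With the labelling batch seen in the spike-ins as a block, limma called 116 genes, 34 higher and 82 lower, of which 110 were among the 1561. With scan day as a block, limma called 0 genes, with 1779 genes at an unadjusted p under 0.05 against 4875 without the block. The count was 316 without CKO 1, 340 without CKO 3, 294 without control 2 and 922 without control 3. It was 2882 without CKO 2 and 2237 without control 1. Of 88 named results that passed, 42 did not pass without CKO 1, 11 without CKO 2, 40 without CKO 3, 4 without control 1, 41 without control 2 and 15 without control 3. The groups did not overlap in 41.8% of genes, where chance gives 10% on average over all ways to split the arrays into equal groups. Genes on the same arrays are not independent, so a single split can lie far from 10%. The share was not computed for other splits.

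**Figure D2:**
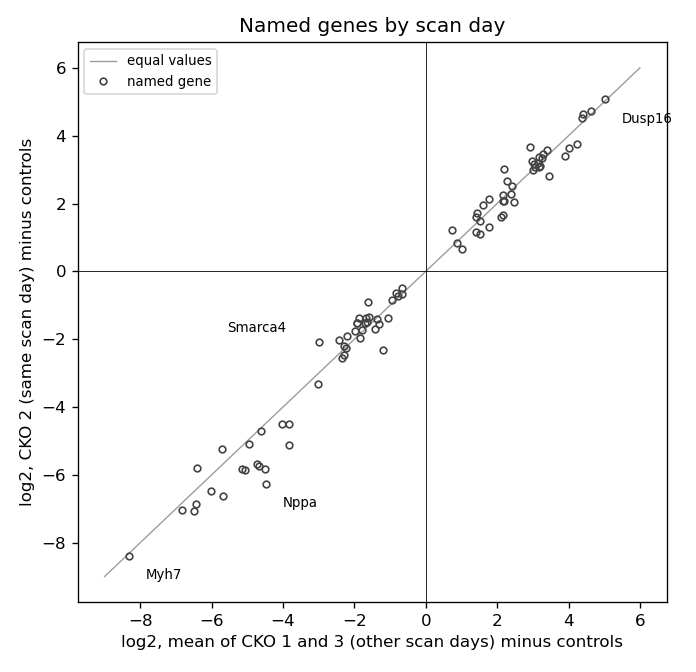
Log2 difference from the mean of the 3 controls for the 89 named genes other than the sex-linked ones. The horizontal axis gives the mean of CKO 1 and CKO 3 (other scan days), the vertical axis CKO 2 (same scan day), and the grey line marks equal values. All 89 genes had the same sign on both axes, which share the same controls. Most were chosen for passing a test that included CKO 2, so the shared sign was largely fixed by that choice.

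Among the 21 tested lists, heart genes had the largest median shift. Of 29 measured heart genes, 17 fell and 1 rose, with a median log2 difference of -2.20 and a same-day median of -2.39. Adjusted over the list alone, 19 fell and 4 rose. The falls covered cardiac myosins and troponins, such as Myh6 (118.5-fold), Myl2 (95.5-fold) and Tnnc1 (log2 difference -4.01). They also included Nppa and Nppb, which encode natriuretic peptides, at -5.06 and -3.37. Their same-day differences were close to these or larger, at -7.02 for Myh6, -6.87 for Myl2 and -6.26 for Nppa. Among the transcription factors of the early heart, Myocd fell by 1.72 and Tbx5 by 1.37 on the log2 scale. Nkx2-5 and Tbx20 did not pass the test, at 0.02 ± 0.17 and -0.10 ± 0.17 (SE). Hand1, a factor of heart and trophoblast, rose by 1.42. The list passed camera with an adjusted p of 5.93e-10 (0.248 with an estimated correlation).

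Many genes activated by p53 were higher in CKO. Of 31 measured p53 targets, 17 rose and none fell, with a median log2 difference of 0.999 and a same-day median of 0.825. Adjusted over the list alone, 22 rose. Cdkn1a, the cell-cycle inhibitor p21, rose 3.82-fold, and Pmaip1 (Noxa), which promotes apoptosis, 4.58-fold. Eda2r rose 5.03-fold and Tap1, which moves peptides into the endoplasmic reticulum for antigen presentation, 9.77-fold, although it was well above background in 1 of 3 controls. Ccng1, Phlda3, Trp53inp1 and Mdm2 also rose, by 1.80, 1.84, 1.48 and 0.94 on the log2 scale. Same-day differences were 1.61 for Cdkn1a, 2.25 for Pmaip1, 2.06 for Eda2r and 3.34 for Tap1. The camera adjusted p was 2.19e-09 (adjusted p = 0.0685 with an estimated correlation). The theme of this list and of the apoptosis, growth arrest and proliferation lists follows the study's title, so they are not independent of the study, and 9 members of the p53 list belong to other lists.

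In the apoptosis machinery, 6 of 38 measured genes rose and 2 fell, or 7 and 3 adjusted over the list alone. Beside Pmaip1, the rises included Bbc3 (Puma), also an initiator of apoptosis, at 2.875-fold, and the death receptor gene Fas at 2.83-fold. Bok fell by 1.585 on the log2 scale. The list as a whole did not pass camera (adjusted p 0.362, median 0.18, same-day median 0.08). Of 29 growth arrest genes 7 rose, or 9 with 3 falling when adjusted over the list alone. The cyclin-dependent kinase inhibitors Cdkn2b, Cdkn2a and Cdkn2c rose by 3.16, 2.45 and 1.11 on the log2 scale. The list's median was -0.15 while its mean was 0.36, and it did not pass camera (direction up, adjusted p 0.656, same-day median 0.11). Of 39 proliferation genes 2 fell, Rrm2 by 0.66 and E2f2 by 0.61 on the log2 scale, and none passed when adjusted over the list alone. That list had a median of -0.10, a same-day median of -0.08 and an adjusted p of 0.203.

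**Figure D3:**
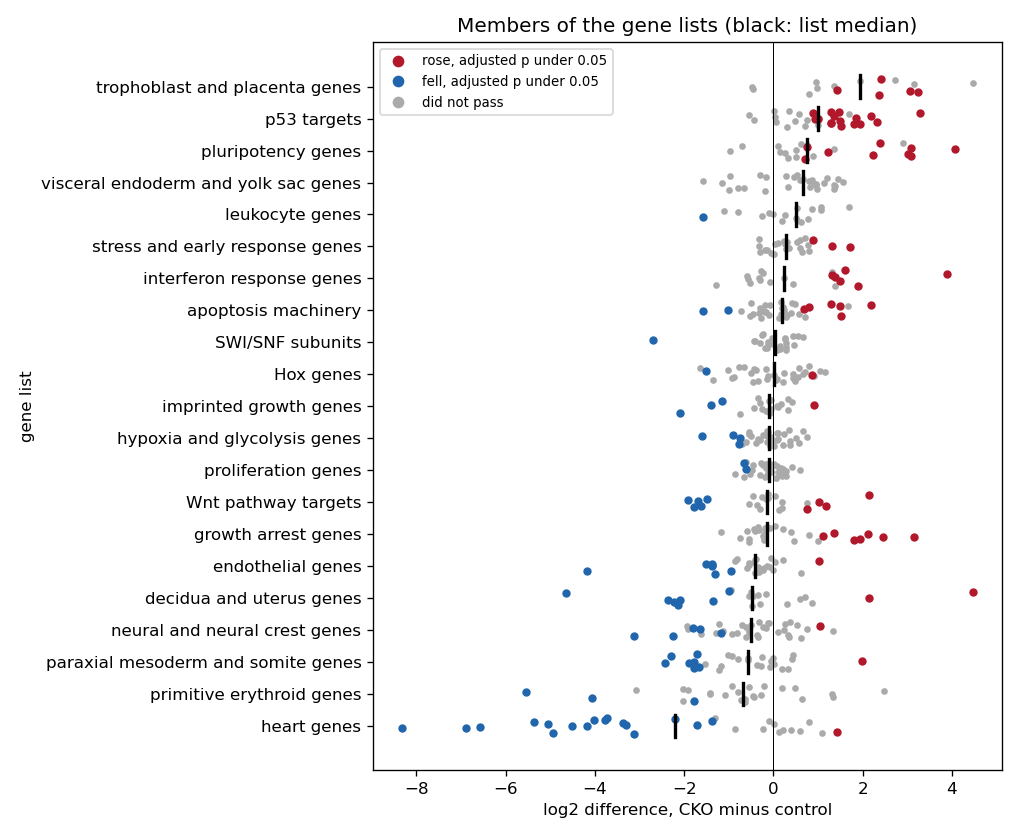
Log2 difference, CKO minus control (horizontal axis), of each measured member of the 21 tested gene lists (vertical axis). Red points rose and blue points fell at an adjusted p under 0.05 over all probes, grey points did not pass, and black bars are list medians. The heart list had the lowest median, -2.20, and the trophoblast list the highest, 1.94.

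Some genes of pluripotent cells and of trophoblast were higher in CKO. Of 22 measured pluripotency genes, 9 rose and none fell, or 11 adjusted over the list alone, with a median of 0.75 and a same-day median of 0.81. Pou5f1 (Oct4) rose 8.42-fold, Dppa4 8.42-fold and Fgf5, a gene of the epiblast, 8.04-fold, in addition to Nanog. Of 15 measured trophoblast and placenta genes, 5 rose and none fell, or 8 adjusted over the list alone, with a median of 1.94 and a same-day median of 2.22. The list's median level was -2.46, 0.07 and -0.49 in controls 1, 2 and 3 and 1.70, 1.64 and 0.38 in CKO 1, 2 and 3, and without control 1 the median difference was 1.43. Elf5, Eomes, Tfap2c and Ascl2, transcription factors of trophoblast progenitors, rose 9.40-fold, 8.41-fold, 5.29-fold and 5.15-fold. Same-day differences were 3.09 for Pou5f1, 3.17 for Dppa4, 2.995 for Fgf5, 3.36 for Elf5, 3.26 for Eomes, 2.67 for Tfap2c and 2.29 for Ascl2. The camera adjusted p was 0.000108 for the pluripotency list (0.258 with an estimated correlation) and 0.000876 for the trophoblast list (0.316 with an estimated correlation). Without control 3 the pluripotency median was 1.15 (adjusted p 1.28e-05).

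Some regional genes of the nervous system and the somites fell. Of 37 neural and neural crest genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone, with a median of -0.51 and a same-day median of -0.55. En1 and En2, which mark the border of midbrain and hindbrain, fell at least 3.90-fold and 4.76-fold, and Pax6 and Otx2 fell 3.49-fold and 3.12-fold. Sox1 rose by 1.04 on the log2 scale. Of 27 genes of paraxial mesoderm and somites 7 fell and 1 rose, or 9 and 1 adjusted over the list alone, with a median of -0.58 and a same-day median of -0.69. Tbx6, Lfng and Meox1, which act in somite formation, fell 4.89-fold, 5.36-fold and 3.69-fold, while Mesp1, a gene of early mesoderm, rose 3.98-fold. Lfng was well above background on 1 of 3 CKO arrays. The adjusted p was 0.00284 for the neural list (0.703 with an estimated correlation) and 0.000876 for the somite list (0.641 with an estimated correlation). All 37 neural and all 27 somite genes were higher in control 1 than in the mean of controls 2 and 3, with medians of 1.003 and 0.908, and without control 1 the neural list did not pass (median -0.14, adjusted p 0.15) and the somite median was -0.34 (adjusted p 0.0113). Of 33 Hox genes, Hoxb5 rose 1.82-fold and Hoxc6 fell 2.85-fold, with 1 rise and 0 falls adjusted over the list alone. The Hox median of 0.02 and mean of -0.06 differed in sign, the same-day median was -0.08 and the adjusted p 0.66. Of 22 Wnt pathway targets 4 rose and 5 fell, or 5 and 5 adjusted over the list alone. Wif1 rose 4.42-fold, while Nkd2, Cdx4 and Nkd1 fell 3.76-fold, 3.41-fold and 3.23-fold. The Wnt median was -0.14, the same-day median -0.10 and the adjusted p 0.401. Control 1 stood above the mean of controls 2 and 3 here too, with medians of 0.69 for Hox and 0.79 for Wnt genes, and without it these list medians were 0.29 and 0.08.

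Some endothelial genes were lower in CKO. Of 30 measured, 7 fell and 1 rose, or 10 and 2 adjusted over the list alone, with a median of -0.40 and a same-day median of -0.43. Emcn (endomucin) fell 18.2-fold, Notch4 2.86-fold and Icam2 2.61-fold, while Sox17 rose by 1.02 on the log2 scale. Same-day differences were -4.495 for Emcn, -1.70 for Notch4 and -1.395 for Icam2. The camera adjusted p was 3.32e-05 (adjusted p = 0.0685 with an estimated correlation).

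Among the 21 tested lists, those of yolk sac endoderm and primitive red cells differed most between control 1 and the other controls. All 29 measured genes of visceral endoderm and yolk sac and all 26 of primitive erythroid cells were lower in control 1 than in the mean of controls 2 and 3. The medians of those differences were -2.84 and -2.78. Between genotypes none of the 29 yolk sac genes passed, nor did any adjusted over the list alone. Their median was 0.65, the same-day median 0.61 and the adjusted p 0.362. Without control 1 the direction turned (median -0.12, adjusted p 0.0113) and 10 of the 29 fell, and the list passed upwards without control 2 (1.04, 0.0365) and without control 3 (1.18, 0.0117). Apoe had the smallest p of these genes, at 1.38 ± 0.56 (SE, adjusted p 0.154). Of the 26 erythroid genes 3 fell, the same number as adjusted over the list alone, with a median of -0.69 and a same-day median of -0.75. They were Hemgn at 46.9-fold, Ermap at 16.7-fold and the water channel gene Aqp1 at 3.45-fold. Their same-day differences were -5.23, -4.49 and -1.525. Hemgn was well above background on 2 and Ermap on 1 of the 3 CKO arrays. The erythroid list passed (adjusted p 0.00708, 0.744 with an estimated correlation), but not without control 2 (median -0.32, adjusted p 0.0571) or control 3 (-0.17, 0.181). Without control 1 its median was -1.73, and 19 of 27 genes fell and 1 rose.

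**Figure D4:**
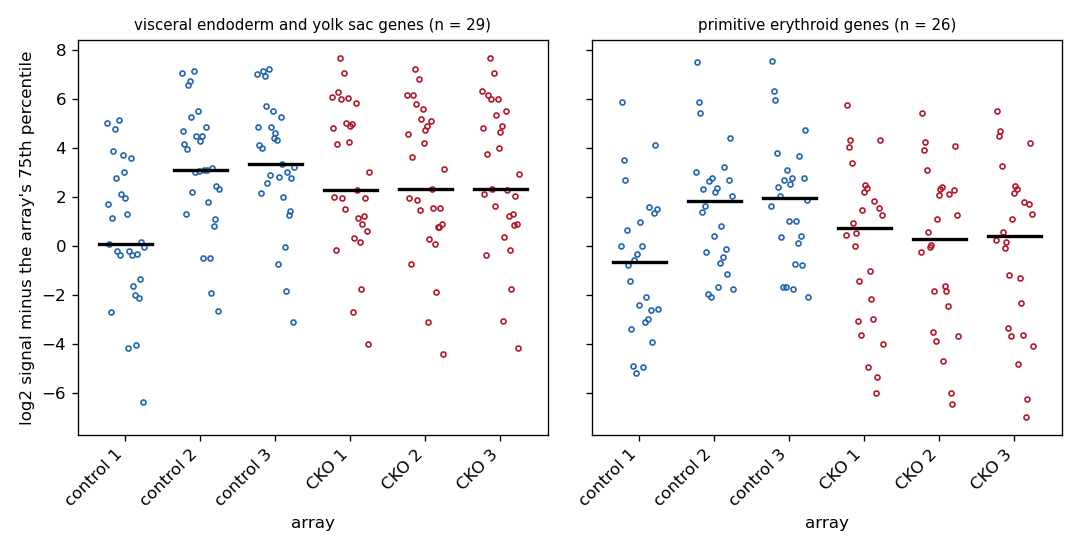
Log2 signal minus the array's 75th percentile (vertical axis) of 29 visceral endoderm and yolk sac genes and 26 primitive erythroid genes on each array (horizontal axis). Circles are genes and black bars are medians. The yolk sac median was 0.10 in control 1, against 3.1 and 3.33 in controls 2 and 3 and 2.29, 2.32 and 2.31 in CKO 1, 2 and 3.

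Of 21 decidua and uterus genes, markers of maternal tissue, 7 fell and 2 rose, or 8 and 2 adjusted over the list alone, with a median and a same-day median of -0.47. Lum, Des and Col6a3, which fell 25.1-fold, 5.13-fold and 4.70-fold, are also genes of embryonic mesenchyme and muscle. Their same-day differences were -4.71, -2.47 and -2.25. Prl8a2, a prolactin-family gene of the decidua, rose by 4.48 ± 1.02 (SE) on the log2 scale and was well above background in 1 of 3 controls. The list's adjusted p was 0.00202 (0.143 with an estimated correlation). Among 17 leukocyte genes only Cd79b changed, with a 2.98-fold fall, and it also passed adjusted over the list alone. The leukocyte median was 0.51, the same-day median -0.05 and the adjusted p 0.656.

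The remaining lists did not pass. Among 24 SWI/SNF subunits Smarca4 alone changed, also when adjusted over the list alone. That list's median of 0.03 and its mean of -0.05 differed in sign, the same-day median was 0.06 and the adjusted p 0.999. Of 19 interferon response genes 6 rose, or 8 with 1 falling when adjusted over the list alone. They included Cxcl10 at 3.71-fold, Usp18 at 3.05-fold and the RNA sensor gene Ifih1 at 2.80-fold (list median 0.23, same-day median -0.07, adjusted p 0.154), and Cxcl10 was well above background in 2 of 3 controls. The interferon median was 0.47 without CKO 2, 0.43 without control 1 and 0.115 without control 3. Of 25 stress and early response genes 3 rose, or 5 adjusted over the list alone: Fos 3.30-fold, Hmox1 2.50-fold and Sesn2 1.855-fold (median 0.29, same-day median 0.37, adjusted p 0.066). The stress list passed without CKO 1 (median 0.33, adjusted p 0.0407) or control 2 (0.27, 0.0254), and without control 3 its median was 0.10 (adjusted p 0.0947). Of 34 hypoxia and glycolysis genes 4 fell, the same number as adjusted over the list alone, led by P4ha2 at 3.02-fold (median -0.10, same-day median -0.18, adjusted p 0.0961), and that list passed without CKO 1 (median -0.13, adjusted p 0.0447). Of 21 imprinted growth genes 3 fell and Ndn rose 1.87-fold, or 4 and 1 adjusted over the list alone. The falls were Dcn at 4.29-fold, Nnat at 2.64-fold and Plagl1 at 2.23-fold (median -0.10, same-day median -0.14, adjusted p 0.0961).

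In all, 9 of the 21 lists passed camera with a preset correlation of 0.01, and 0 passed with the correlation estimated from the data. With 1 array left out, the medians of lists that had not passed also moved. They were -0.025 without CKO 3 and 0.008 without control 1 for proliferation, -0.053 to -0.061 without CKO 2, control 1 or control 2 for hypoxia, -0.055 without CKO 2 for imprinted genes, and 0.31 without CKO 3 and 0.23 without control 1 for leukocyte genes. The lists with the smallest p with an estimated correlation were the p53 targets and the endothelial genes.

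Sex-linked genes were read as a check of the samples. Xist, transcribed from the inactive X chromosome, stood at -5.86, -8.54 and 3.61 in controls 1, 2 and 3 and at -0.91, 0.65 and 1.66 in CKO 1, 2 and 3. The Y-linked Eif2s3y stood at 1.60, 0.49 and -8.78 in the controls and at 1.09, 1.29 and 0.51 in CKO. All 3 CKO samples had both transcripts well above background, as did control 1. Xist was not well above background in control 2, nor Eif2s3y in control 3. Neither these genes nor Ddx3y, Kdm5d and Uty passed the test between genotypes, with limma adjusted p from 0.368 to 0.861. Without control 3, Xist (log2 difference 7.66, adjusted p 0.0209) and Kdm5d (-1.83, 0.0298) passed.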

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

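The look at the control spots was chosen after the files were seen. The bright corner spots, which position the grid and carry no sample RNA, read 79879.8 units on CKO 1 and 51873.9 units on CKO 3. On the 3 controls they read 3481.9 to 4473.1 units, and on CKO 2 4539.6 units. These spots were in no comparison, and stood out because their signal was above that of the controls. The brightest spike-in parted the same 2 arrays from the other 4 in the opposite direction. Both arrays were scanned on days without a control, so that a difference between days and a difference in labelling are not separable there.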

How the results depend on the processing

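The test with the labelling batch as a block was chosen after the results were seen, and the others were planned. Of the 15025 genes, 1561 changed. The count was 686 without a filter on dim probes (641 shared), 6900 with array weights (1561 shared, with a convergence warning), 260 at an adjusted p of 0.01, 116 with the labelling batch as a block (110 shared), 0 with scan day as a block (1779 at an unadjusted p under 0.05 by limma), and 294 to 2882 with 1 array left out. Other settings gave 1147 to 1992 genes. No label says whether the numbers of the replicates pair the samples. With the replicate block the count was 548 (516 shared) and Smarca4 stood at -2.688 (limma adjusted p 0.0538). Smarca4 stood at -2.084 with scan day (adjusted p 0.293) or the labelling batch (0.137) as a block, and at -2.99 to -2.41 with 1 array left out. With an estimated correlation 0 lists passed, and fry called 11. The direction of the list test turned for 6 lists. For SWI/SNF subunits the medians were 0.029 (quantile), 0.05 (normexp), 0.031 (stricter filter, replicate block and fry), 0.11 (array weights), 0.063 (both batch blocks) and -0.043 to 0.158 (1 array left out). For Hox genes they were 0.186 (array weights), -0.075 (both batch blocks), 0.02 (fry) and -0.163 to 0.294 (1 array left out). Yolk sac genes had 0.113 with array weights and -0.121 to 1.183 with 1 array left out. Leukocyte genes had -0.051 with either batch block and 0.228 to 0.685 with 1 array left out. With 1 array left out, growth arrest genes had -0.13 to -0.054 and Wnt targets -0.324 to 0.084. Among the sex-linked genes, none of which passed with all arrays, Xist (7.662, adjusted p 0.0209) and Kdm5d (0.0298) passed without control 3. Kdm5d had -0.539 (normexp), -0.082 (array weights) and -1.832 to 1.733 (1 array left out), and Uty had -0.013 (normexp) and -0.869 to 1.72. Ddx3y had -0.768 to 3.893 and Eif2s3y -0.083 to 5.105 with 1 array left out. The cause was not tested, except that blocks leave CKO 2 alone against the controls and a stricter threshold passes fewer genes. A slide could not be a fixed block, since the 3 controls share 1 slide that holds no CKO array. Signal over background limits the dim genes: 74 changed genes were dim on all controls and 39 on all CKO arrays.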

Other observations

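The tests of scan day or labelling batch, of the labelling of control 1 and of other splits were chosen only after the results were seen, and so was that of the heart transcription factors. The sarcomere genes and these factors belong to the fixed heart list, which had been tested. The other gene lists of this part were written after the first results but before their own members were looked at. After the first results of these lists, 3 genes that belong to the fixed lists (Sp5, Dkk1 and Peg10) were dropped, the sarcomere list was reduced to 14 genes of the fixed heart list, and a p under 0.05 with an estimated correlation was added to what a group had to meet to count as higher. The batch test of the trophoblast and pluripotency genes was first run on the 14 that rose, which had been chosen with CKO 2 among the arrays and whose outcome was thereby fixed, and then on all members. That calls hold with the batch as a block was asked for from then on. Under the criterion as first written, which asked for a median above 0.3 and a preset p under 0.05, the primitive streak, antigen presentation and synaptic lists would have passed.

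Of 22 measured germline genes other than Dnmt3l and Piwil4, 8 rose and 1 fell. Sycp3, a part of the synaptonemal complex of meiosis, rose by 2.08 on the log2 scale, Sohlh2 by 1.82 and Piwil2, which acts in the piRNA pathway and was well above background in 1 of 3 controls, by 1.57, while Tdrd7 fell by 0.95. That germline genes are higher as a group is a hypothesis that the rise of Dnmt3l gave. The median of the list was 1.056 and its same-day median 1.003, with a camera p of 0.000168 (0.00084 adjusted over 5 added lists). With an estimated correlation the p was 0.0144, which failed the correction at 0.072. The highest absolute median of the other 9 splits of the arrays was 0.478.

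Genes of MHC class I antigen presentation other than Psmb8, Psmb9 and Tap1 had a median of 0.335, and 4 of 13 rose: Tap2 by 3.77, Tapbp by 1.47, H2-D1 by 1.28 and H2-T23 by 0.64 on the log2 scale. Tap2 was well above background in 1 of 3 controls. The camera p was 0.0369, or 0.2 with an estimated correlation, so that a rise of the group may or may not be present. Synaptic and neurotransmitter genes other than the 8 that led to the idea had a median of 0.488, and 8 of 35 rose and 2 fell. Nefm and Nefl, of the neurofilaments, rose by 2.07 and 1.81. The same-day median was 0.09, the p 0.0387 or 0.549 with an estimated correlation, and 2 of the 10 splits had a median as large, so that no group shift was shown.

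Of 14 sarcomere genes 13 fell, with a median of -4.09 over all 14. This may be biological or come from the samples' make-up. Scan day or labelling batch as the whole cause is argued against by CKO 2, whose median difference from the same-day controls was -4.272, and -4.88, -3.97 and -4.34 against controls 1, 2 and 3, and 11 of the 13 also fell with the labelling batch as a block. The transcription factors Nkx2-5, Tbx5, Tbx20 and Myocd differed less, with a median of -0.732 (0.02, -1.37, -0.10 and -1.72 in that order). They were picked after their values were seen and are also expressed outside the heart. Other transcription factors of the fixed heart list went both ways and were not in that median. Hand1, Gata4, Hand2, Hey2, Irx4 and Gata6 differed by 1.42, 1.10, 0.59, 0.40, 0.22 and 0.12, and Mef2c and Isl1 by -0.86 and -0.24. A smaller share of heart tissue as a cause is therefore left open. An earlier stage stays open: 20 genes of the primitive streak stage had a median of 0.625, with a p of 0.00191 but 0.25 with an estimated correlation, and 4 rose (Wnt8a, Frzb, Lhx1 and Bmp4).

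Of 37 trophoblast and pluripotency genes 14 rose. Over all 37, chosen without regard to their calls, CKO 2 stood above the same-day controls by a median of 1.102, and by 1.70, 0.99 and 0.71 above controls 1, 2 and 3. With the labelling batch as a block only Elf5 of the 14 passed, but the SE widened while the difference moved by less than it for Pou5f1 (3.07 ± 0.38 before, 3.09 ± 0.59 with the block, SE) and Eomes (3.07 ± 0.58 and 3.26 ± 0.89). Utf1, in contrast, moved from 2.40 ± 0.26 (SE) to 1.94 with the block. Whether both lists pass camera with the block cannot decide the matter, since it leaves CKO 2 alone against the controls. Scan day or labelling batch therefore stays open as a cause. A larger share of trophoblast tissue is likewise open for the trophoblast genes. An earlier stage, weighed above for the sarcomere genes, was not tested as a cause of these rises. Over 19 other trophoblast genes the median was 0.416, the same-day median 0.255 and the camera p 0.625. Among them Gata2 and Lifr rose by 2.08 and 1.36 while Krt7 and Arid3a fell by 2.32 and 0.76. The placental hormone gene Prl3d1 stood at 0.999, 0.66 and -2.06 in CKO 1, 2 and 3 and at -4.59, -3.83 and -1.45 in controls 1, 2 and 3.

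Control 1 had lower levels of yolk sac and erythroid genes than controls 2 and 3, by 7.14-fold and 6.88-fold in the median. Less yolk sac tissue in that sample is a candidate explanation, since 24 of 26 yolk sac endoderm genes outside the fixed lists were also lower, with a median of -2.211. Afp stood at 5.02 in control 1 and at 7.08 and 7.01 in controls 2 and 3, and Apoa1 at 1.73, 4.69 and 4.875. The share of spots well above background was 69.27% in control 1, against 69.18% and 68.47% in controls 2 and 3. That share gave no sign of weaker labelling, but differences this small cannot exclude it. The design names no biological difference among the controls, so none was tested.

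With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1561 genes, as 1 of 10, and the highest other 0, with up to 1053 genes at an unadjusted p under 0.05. For lists past the threshold, 8 of the 10 splits gave as many as the real 9, and the highest other gave 11, for CKO 1, CKO 2 and control 3 against the rest. Of the other 3 splits that join CKO 1 and CKO 3, the arrays with low spike-in signal, 1 gave 6 lists and 2 gave 9, and with the labelling batch inferred from that signal as a block 11 lists passed. Camera with a preset correlation called 6 to 11 lists in each of the 10 splits.

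Xist and Eif2s3y were both well above background in the 3 CKO samples and in control 1, where Xist stood at -5.86 against -0.91 or more in CKO. Control 2 lacked Xist and control 3 lacked Eif2s3y at that level. Some samples may be pools of embryos of both sexes, which was not tested, and samples may then differ in what each stands for. Without control 3, Xist differed by 7.662 on the log2 scale.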
